A study of Homo sapiens with 6 samples.

How the data were processed

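RNA sequencing was carried out on A549 cells, a human lung adenocarcinoma line of epithelial origin, 48 hours after transfection with small interfering RNA (siRNA). Of the 6 libraries, 3 came from cells given an siRNA against GSE1 and 3 from cells given a negative control siRNA. Per the labels' protocols, total RNA was extracted with TRIzol, 500 ng of it entered each library, and libraries were made with the Illumina TruSeq RNA Sample Preparation Kit. The siRNA sequences are not given in the sources used here. The labels number the replicates 1 to 3 in each group and do not say whether they were separate cultures on separate days. The p-values of single genes below therefore measure only the spread between these libraries, which may be technical. P-values of ontology terms and sequence sites are taken over genes and do not measure that spread. Those of gene lists by camera also depend on an assumed correlation between genes.

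The authors deposited one table of 60612 Ensembl genes with whole-number read counts and FPKM (fragments scaled to exon length and library total) for each library, beside the exonic length, position, symbol and gene ontology terms of each gene. The sources differ on how the table was made. Per the submitters' processing notes, bcl2fastq, FastQC, cutadapt, HISAT2, StringTie 1.3.3b, HTSeq and edgeR were used with the hg38 build, with no roles or order given. Per the series text, reads were instead mapped with STAR, expressed as RPKM and tested with DESeq2. The deposited counts carry no normalization. Each deposited FPKM value equals the count divided by the exonic length and by the library's summed counts, within a tolerance of 0.0051, in 100% of the cells of every library. The gene annotation release behind the counts is not given in the sources used here. Of the gene identifiers, 58394 occurred in GENCODE release 29, and 77.0% of those had the same chromosome, start, end and strand in both. Coordinates below are those of the deposited table in hg38.

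Library totals ran from 14475992 to 20755506 counts. At these depths a gene with 100 counts in a library carries a counting error of 10%, and the biological coefficient of variation across all genes was estimated at 7.0%. Trimmed mean of M values (TMM) factors lay between 0.980 and 1.01. Because the test fixed in advance assumed a table of FPKM alone and the table turned out to hold counts, the edgeR quasi-likelihood test named in advance for that case became the main test. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15937. The model held the group alone, with no block on the replicate number. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. A stricter count used an adjusted p of at most 0.001 and an absolute log2 fold change of at least 0.5, after the limits in the series text, whose limit on the RPKM ratio was read as a log2 fold change. Fold changes come from the model and are scaled by TMM, while FPKM are printed as deposited, so their quotients differ slightly. For GSE1 and KLF6 an exact two-sided permutation test on log2(FPKM + 1) was added.

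A total of 31 gene lists were fixed before the data were examined, and 29 had the 5 tested members required. They were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, on log2 CPM (counts scaled to library size) with a prior count of 2, and again with the correlation estimated per list. The fry test was also run, which asks whether the genes of a list move one way on balance and compares them with no other genes. Named genes followed a rule fixed at the same time. It takes GSE1 and KLF6, then the 12 largest increases and 12 largest decreases among genes past the threshold with a gene symbol that is not a clone or identifier name, at least 5 FPKM in the higher group and no overlap between groups. From each list it takes up to 4 passing members with the smallest adjusted p, or, where none passes, the 2 most abundant. Genes named outside that rule were chosen after their values were seen and are identified as such.

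Ontology terms in the deposited table were tested for over-representation by a one-sided hypergeometric test over 10556 protein-coding tested genes that carry a process term, for the 1360 terms of 10 to 300 such genes, with Benjamini-Hochberg adjustment per direction. Sequence sites of 7 bases were compared with fold changes over 12820 genes with an annotated 3' untranslated region (UTR) of at least 50 bases in GENCODE release 29. That regression was adjusted for length, GC content and abundance, with 200 permutations of the fold changes over genes. The isoform with the longest coding sequence stood for each gene.

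The count test was tested on simulated counts with the means, depths and dispersions of these libraries. Of 15699 simulated genes past the filter, 49 had been changed at each fold. The siGSE1 comparison simulated in this way recovered 22.4% of genes changed 1.25-fold, 65.3% at 1.5-fold, 83.7% at 2-fold and 98.0% at 4-fold, with 4 calls among unchanged genes. Only 200 genes were changed there, against 3167 called in the data. The adjusted threshold is harder to pass with so few, so these shares do not carry over to the data. The list test was run with 29 lists on a further simulation, in which 1 list was raised 1.25-fold. It called the 1 raised list and 0 unchanged lists, with lists that share a raised gene left out. Genes were drawn independently there, so this cannot show how often lists whose genes move together are called falsely. In the site regression, an effect of -0.3 placed in permuted fold changes of the 12820 genes was recovered as -0.293.

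Alternatives covered the low-count filter, the scaling, limma on log2 FPKM with several pseudocounts, DESeq2, a replicate block, removal of GC and length trends, and leaving out each library in turn. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, scipy 1.17.1 and matplotlib 3.10.9. Genes that overlap another gene cannot be told apart from it where counting ignored strand, and the strand setting is not given in the sources used here. Counts of ribosomal protein genes and histone genes may be split with near-identical copies.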

Results

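The 6 libraries fell into 2 groups of 3, A549 cells given an siRNA against GSE1 (siGSE1) and A549 cells given a negative control siRNA. Control replicates 1, 2 and 3 held 20525237, 20755506 and 14475992 counts, and siGSE1 replicates 1, 2 and 3 held 17521807, 19327027 and 19914346. Between 23128 and 24059 genes had a count in each library. The 10 most abundant genes took 9.34% to 9.49% of the counts in the control libraries and 8.43% to 8.63% in the siGSE1 libraries. Genes of the mitochondrial genome took 7.38% to 7.48% and 6.70% to 6.95%. Control replicate 2 stood apart from the other libraries of its group. The chi-square per degree of freedom of its counts was 10.1 against control replicate 1 and 8.97 against control replicate 3, where the other control pair had 4.60 and the siGSE1 pairs had 2.49 to 3.32. The first principal component held 39.0% of the variance and separated the groups, and the second held 18.2% and set control replicate 2 at -27.6 against 22.6 for control replicate 3.

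The series title names KLF6, so the targeted gene and KLF6 were taken first. GSE1, which encodes a protein found with the CoREST repressor complex, fell to 49.0% of its control level 48 hours after transfection. KLF6, a zinc finger transcription factor, rose 2.08-fold. GSE1 (ENSG00000131149, chromosome 16, 85169525 to 85676204, plus strand) had 7.78 ± 0.36 FPKM in control cells and 3.88 ± 0.17 in siGSE1 cells (SD, n = 3 each), a log2 fold change of -1.03 (SE 0.06, edgeR adjusted p = 2.14e-08). KLF6 (ENSG00000067082, chromosome 10, 3775996 to 3785281, minus strand) had 7.32 ± 0.10 FPKM in control cells and 15.5 ± 0.15 in siGSE1 cells (SD, n = 3 each), a log2 fold change of 1.06 (SE 0.06, edgeR adjusted p = 1.05e-08). Counts per library were 1533 to 2239 for GSE1 in control cells and 899 to 1049 in siGSE1 cells, and 647 to 938 and 1650 to 1909 for KLF6. Of the 7 annotated KLF6 transcripts, 0 hold TCGGAGA or CGGAGAA, sequences whose carriers lay higher in siGSE1 cells as a group, and 6 hold GGAGAAA, of which the same is true. For both genes the 3 values of one group lay beyond all 3 of the other. The exact two-sided permutation p was 0.1 for each gene, the smallest that 3 libraries against 3 allow.

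**Figure D1:**
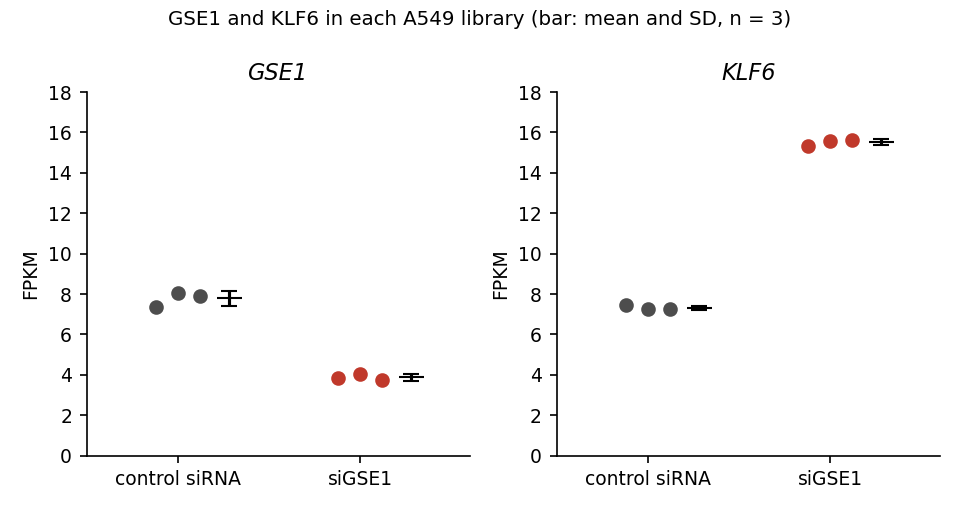
FPKM of GSE1 (left) and KLF6 (right) in each A549 library (points), with the mean and SD of the 3 libraries per group (bars). GSE1 lay between 7.37 and 8.06 in control cells and between 3.73 and 4.06 in siGSE1 cells, and KLF6 between 7.25 and 7.44 and between 15.3 and 15.6.

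The stated aim was to find the genes and pathways that GSE1 influences, which the comparison of all genes addresses. Among the 12 largest increases under the naming rule, with its limits on abundance and overlap, were COL5A1, a fibrillar collagen chain, IL11, a cytokine, B4GALT1, a galactosyltransferase of the Golgi, PMEPA1, a feedback inhibitor of TGF-beta signaling, and TPM4, a tropomyosin of actin filaments. The 12 largest decreases under that rule included SUSD2, a membrane protein, HMGCS1, an early enzyme of cholesterol synthesis, and CCND1, the cyclin D1 of the G1 phase. Most changes were small, with a median of 1.28-fold among genes past the threshold. B4GALT1 rose 2.85-fold, from 50.7 ± 4.11 to 147 ± 3.57 FPKM (SD, n = 3 each), a log2 fold change of 1.51 (SE 0.06, adjusted p = 3.28e-10). HMGCS1 fell 2.66-fold, from 35.2 ± 2.49 to 13.5 ± 0.41 FPKM, a log2 fold change of -1.41 (SE 0.06, adjusted p = 1.43e-09).

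Of 15937 genes tested, 3167 (19.9%) changed, 1730 of them higher and 1437 lower in siGSE1 cells, and 12770 did not pass the threshold. With FPKM rescaled to a fixed sum per library (TPM), 2544 genes were higher and 929 lower, so the share of changed genes that rose went from 54.6% to 73.3%. With GC and length trends removed, an alternative added after the data were seen, 1527 were higher and 1694 lower, a share of 47.4%. The stricter thresholds were passed by 406 genes, 258 higher and 148 lower. A change of at least 2-fold was found for 121 higher and 91 lower genes. The 2 groups did not overlap in 3086 of the changed genes and in 36.1% of all genes tested, where chance gives 10%. Without control replicate 2, 3562 genes changed and 530 passed the stricter thresholds. The counts fell to 2055 and 266 without siGSE1 replicate 2 and to 1863 and 201 without siGSE1 replicate 3, and the stricter count was 261 without siGSE1 replicate 1.

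COL5A1 rose from 3.75 ± 1.62 to 12.2 ± 0.87 FPKM, a log2 fold change of 1.70 (SE 0.21, adjusted p = 3.26e-05). IL11 rose from 1.80 ± 0.74 to 5.25 ± 0.40 FPKM and PMEPA1 from 22.0 ± 9.29 to 60.9 ± 1.86 FPKM (SD, n = 3 each), log2 fold changes of 1.55 (SE 0.21) and 1.45 (SE 0.21). TPM4 rose from 17.3 ± 1.81 to 43.5 ± 1.18 FPKM, a log2 fold change of 1.31 (SE 0.07). The metalloprotease gene ADAM19 rose by 1.44 on the log2 scale, the G-protein regulator RGS2 by 1.36, the endoplasmic reticulum chaperone gene MESD by 1.24, the SNARE protein gene STX12 by 1.21, the secreted glycoprotein gene STC1 by 1.20 and the activin antagonist FST by 1.15. In control replicates 1, 2 and 3, COL5A1 had 4.65, 1.88 and 4.73 FPKM and IL11 2.04, 0.97 and 2.4. PMEPA1 had 27.1, 11.3 and 27.7 there and ADAM19 2.71, 1.42 and 2.52, whereas TPM4 had 16.6, 19.3 and 15.9. The low values in control replicate 2 enlarge the folds of COL5A1, IL11, PMEPA1 and ADAM19. The small nucleolar RNA SNORD62B had the largest log2 fold change under the naming rule, 1.72 (SE 0.52, adjusted p = 0.0278), at 2.57 ± 0.80 and 8.63 ± 2.21 FPKM. Its gene spans only 131490486 to 131490571 on chromosome 9, so these FPKM stand for few reads. It met the rule's FPKM limit because it is so short. With edgeR's robust prior, added after the data were seen, PMEPA1 had an adjusted p of 0.0742 and lost its call. The 7-base sequence TCGGAGA, whose carriers lay higher in siGSE1 cells as a group, occurs in the 3' UTR of B4GALT1 and TPM4, and of IER2, LTBP2 and NOLC1 among the genes named further on, and in the coding sequence of COL5A1, PMEPA1, BHLHE40, TNC, PFKL and HSPB1. It also occurs in the coding sequence of SUSD2, HK1, HERC5 and FASN, which fell. The sequence CGGAGAA, whose carriers also lay higher as a group, occurs in the 3' UTR of MESD and RHOB. It lies in the coding sequence of TGFBI and BIRC5, which rose, and of HSPA1B and GSE1, which fell.

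SUSD2 fell from 5.14 ± 0.48 to 1.93 ± 0.34 FPKM, a log2 fold change of -1.44 (SE 0.12, adjusted p = 9.37e-07). CCND1 fell from 111 ± 11.8 to 60.3 ± 0.88 FPKM (SD, n = 3 each), a log2 fold change of -0.90 (SE 0.07, adjusted p = 2.44e-07). The glutathione-cycle enzyme gene GGCT had a log2 fold change of -1.08, the neurofilament gene NEFL of -1.06, the homeobox gene MSX2 of -0.99 and CDC37L1, related to the cochaperone CDC37, of -0.97. GNE, the first enzyme of sialic acid synthesis, had -0.96, the chromatin protein gene MORF4L1 -0.92, the proton pump subunit gene ATP6V1A -0.91 and the SUMO protease gene SENP3 -0.91.

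**Figure D2:**
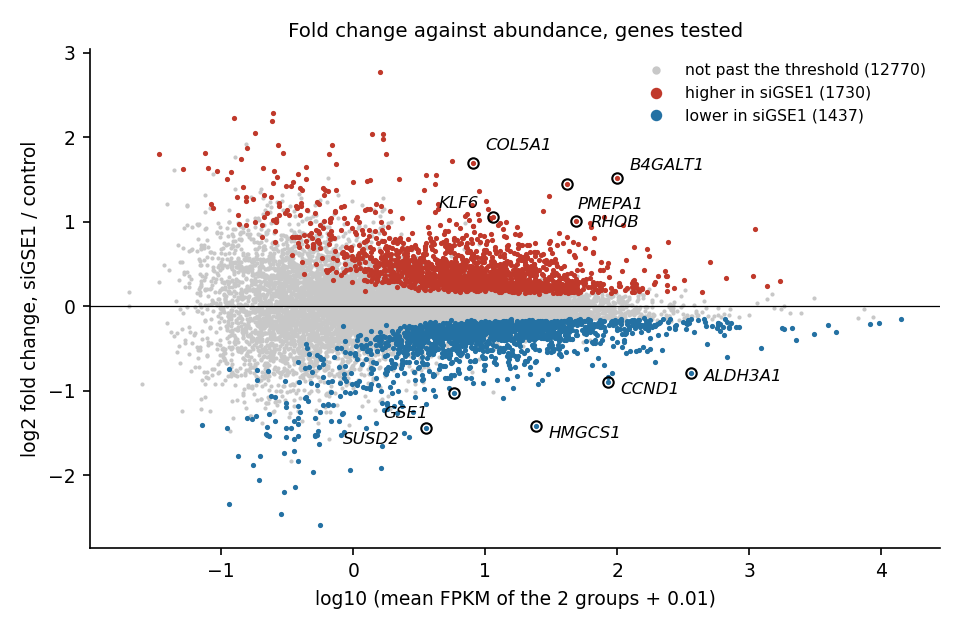
Log2 fold change (siGSE1 over control) of each of the 15937 genes tested against the log10 of its mean FPKM over both groups plus 0.01. Red points mark the 1730 genes higher and blue points the 1437 genes lower in siGSE1 cells, grey points the 12770 genes not past the threshold, and circles mark the genes named on the plot, among them B4GALT1 at 1.51 and HMGCS1 at -1.41.

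Targets of TGF-beta, a growth factor that drives matrix production, included more that rose than fell. Of 20 tested targets, 12 rose, 4 fell and 4 did not pass, and adjusted over the list alone 13 rose and 4 fell. The median log2 fold change was 0.34 (camera adjusted p = 1.45e-04, and adjusted p = 0.340 with an estimated correlation). The receptor gene TGFBR1 rose from 7.05 ± 1.24 to 14.6 ± 0.88 FPKM, LTBP2, a binding protein of the extracellular matrix, from 3.50 ± 0.77 to 7.17 ± 0.23, and the repressor gene BHLHE40 from 69.8 ± 2.38 to 98.3 ± 2.79 (SD, n = 3 each). The 4 that fell were ID2 (log2 fold change -0.83), ID1 (-0.34), SMAD6 (-0.20) and TGIF1 (-0.15), of which ID1 and SMAD6 are known as targets of BMP signaling, and the last 3 of the 4 were named after their values were seen. Relative to the control mean the list median was 0.05, -0.11 and 0.09 in control replicates 1, 2 and 3 and 0.33 to 0.39 in the siGSE1 libraries. Without control replicate 2 it was 0.29 (adjusted p = 1.02e-05). The sequence TCGGAGA or CGGAGAA occurs in the 3' UTR or coding sequence of 6 of the 20 members, all 6 of which rose, and the median of the others was 0.21. Carriers in other lists differed, with 5 of 7 rising in the adhesion and motility list, 1 of 7 in the mitosis list and 0 of 7 in the interferon list. Without siGSE1 replicate 1 or 2, 2 targets fell. Under edgeR's robust prior 9 targets rose and 4 fell.

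Of 25 tested mesenchymal genes, 9 rose, 1 fell and 15 did not pass, and adjusted over the list alone 11 rose and 1 fell, with a median of 0.21 (camera adjusted p = 0.00329, adjusted p = 0.340 with an estimated correlation and 0.0513 by fry). The matrix glycoprotein gene THBS1 rose by 0.79 on the log2 scale, the fibronectin receptor subunit ITGA5 from 10.8 ± 1.49 to 16.8 ± 0.85 FPKM, and TNC, a matrix protein of low abundance here, from 0.55 ± 0.12 to 1.15 ± 0.08 (SD, n = 3 each). TGFBI rose by 0.67 on the log2 scale, with an adjusted p of 0.104 under edgeR's robust prior. SPARC, a secreted matrix protein named after its values were seen, fell from 0.47 ± 0.27 to 0.10 ± 0.04 FPKM. This list's median was -0.17 in control replicate 2, 0.09 and 0.07 in the other control libraries and 0.19 to 0.28 in the siGSE1 libraries, and without that replicate it was 0.16 (adjusted p = 0.0113). Without siGSE1 replicate 3, 5 members rose.

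Among 32 tested genes of adhesion and motility, 14 rose, 4 fell and 14 did not pass, and adjusted over the list alone 17 rose and 4 fell. The median was 0.14 (camera adjusted p = 0.00179, and adjusted p = 0.340 with an estimated correlation), and 9 rose without siGSE1 replicate 1 and 7 without siGSE1 replicate 3. Under edgeR's robust prior 12 rose and 4 fell. RHOB, a small GTPase of endosomes and actin, rose from 31.9 ± 1.31 to 65.0 ± 2.49 FPKM and RAC1, a GTPase of membrane ruffling, from 51.1 ± 4.67 to 80.3 ± 2.94. ITGB4, the integrin chain of hemidesmosomes, fell from 77.0 ± 2.96 to 57.7 ± 1.09 and CDC42, a GTPase of filopodia, from 7.36 ± 0.36 to 5.78 ± 0.42 (SD, n = 3 each). Of 22 tested epithelial genes, 0 rose, 4 fell and 18 did not pass, and adjusted over the list alone 5 fell (camera adjusted p = 0.219). The tight junction gene CLDN4 fell by 0.72 on the log2 scale and the keratin gene KRT8 by 0.26, and the list median of -0.02 was above 0 with TPM scaling and without control replicate 2. Without siGSE1 replicates 1, 2 and 3, 1, 1 and 2 fell, without control replicate 3, 1 rose, and with TPM scaling 1 rose and 2 fell. Under edgeR's robust prior 0 epithelial genes rose and 2 fell.

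Markers of other cell types were mostly near the floor, with 12 of 14 leukocyte, 9 of 12 fibroblast and 9 of 10 endothelial markers under 1 FPKM in both groups. Of 6 tested fibroblast markers, 2 rose, 0 fell and 4 did not pass, the same as adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0104, and adjusted p = 0.340 with an estimated correlation). The 2 were COL5A1 and the smooth muscle actin gene ACTA2, which went from 2.63 ± 0.04 to 4.08 ± 0.68 FPKM (SD, n = 3 each). The fibroblast median was 0.47, -0.55 and 0.17 in control replicates 1, 2 and 3 and 0.55 to 0.79 in the siGSE1 libraries, and it was 0.47 without control replicate 2 (adjusted p = 0.0113) and 1.09 without control replicate 1. With no low-count filter the fibroblast list had an adjusted p of 0.0556. Among 3 tested leukocyte and 2 tested endothelial markers, too few for the list test, the endothelial adhesion gene ESAM rose (log2 fold change 1.15) and none fell, in the counts over all genes and adjusted over the list alone.

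The KLF family list has KLF6 as a member, which the series title names, so its direction is not independent of the result above. Of 12 tested members, 5 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.0147, and adjusted p = 0.340 with an estimated correlation), and under limma on log2(FPKM + 1) the adjusted p was 0.101. The median was 0.04 without control replicate 1, 0.06 without siGSE1 replicate 1, 0.15 with TPM scaling, 0.04 under quantile normalization and 0.05 with GC and length trends removed. Besides KLF6, the TGF-beta inducible KLF10 rose from 18.5 ± 1.77 to 26.0 ± 0.85 FPKM, KLF7 from 4.84 ± 0.75 to 7.05 ± 0.36 and KLF2 from 1.22 ± 0.47 to 2.43 ± 0.17 (SD, n = 3 each). Genes of the CoREST and histone deacetylase complex did not move as a list, with 1 of 17 rising, 1 falling and 15 not passing, the same adjusted over the list alone (camera adjusted p = 0.851). The scaffold gene RCOR1 fell by 0.44 and the reader gene PHF21A rose by 0.30 on the log2 scale, 0 rose without siGSE1 replicate 3, 2 fell without control replicate 2, and the list median of -0.00 was above 0 with TPM scaling, without TMM, with no low-count filter, without control replicate 1 and under limma on log2 FPKM without quantile normalization.

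Immediate early genes, which respond within minutes to growth signals, included 12 that rose, 3 that fell and 9 that did not pass among 24 tested. Adjusted over the list alone 13 rose and 4 fell, with a median of 0.19 (camera adjusted p = 0.00904, and adjusted p = 0.340 with an estimated correlation). IER2 rose from 15.4 ± 0.33 to 25.7 ± 1.62 FPKM, IER3 from 50.5 ± 3.09 to 80.3 ± 3.19 and JUN, a subunit of AP-1, from 15.9 ± 2.03 to 26.6 ± 0.73 (SD, n = 3 each). DUSP5, a phosphatase of ERK, fell by 0.54 on the log2 scale. Under edgeR's robust prior 10 immediate early genes rose and 2 fell. Targets of ATF4 and the unfolded protein response had 14 rising, 5 falling and 8 not passing of 27, and adjusted over the list alone 15 rose and 6 fell. Their median was 0.21 (camera adjusted p = 0.0179, and adjusted p = 0.340 with an estimated correlation). Without siGSE1 replicates 1, 2 and 3 the numbers were 8, 10 and 9 rising and 2, 2 and 0 falling, 3 fell without control replicate 3, and with TPM scaling 1 fell. The endoplasmic reticulum chaperone gene HSPA5 rose from 247 ± 7.26 to 292 ± 4.56 FPKM and EDEM1, which targets misfolded proteins for degradation, from 13.9 ± 0.48 to 17.2 ± 0.25. CHAC1 (-0.86) and DDIT3 (-0.47), known ATF4 targets named after their values were seen, fell. Of 10 tested replication histone genes, 3 rose, 0 fell and 7 did not pass, the same adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.00320, and adjusted p = 0.340 with an estimated correlation). H2BC5 had 9.40 ± 2.26 and 19.1 ± 1.10 FPKM and H2BC12 93.9 ± 10.4 and 140 ± 9.22 in control and siGSE1 cells.

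Targets of NRF2, the transcription factor of the oxidative stress response, were mostly lower. Of 28 tested, 21 fell, 1 rose and 6 did not pass, and adjusted over the list alone 24 fell and 2 rose. The median was -0.25 (camera adjusted p = 4.94e-13, and adjusted p = 0.340 with an estimated correlation). Thioredoxin reductase TXNRD1 fell from 236 ± 12.9 to 152 ± 4.53 FPKM and the aldehyde dehydrogenase gene ALDH3A1 from 454 ± 43.0 to 268 ± 9.42 (SD, n = 3 each). The sulfiredoxin gene SRXN1 fell from 28.8 ± 0.85 to 18.5 ± 1.17 FPKM and GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, from 18.2 ± 1.59 to 11.7 ± 0.68. ME1, the cytosolic malic enzyme named after its values were seen, was the member that rose (log2 fold change 0.30). It lost that call without control replicate 1 or 3, without siGSE1 replicate 1, 2 or 3, with edgeR's robust prior and under limma in each form, where 0 members rose, and without control replicate 2, 2 rose.

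Of 30 tested interferon response genes 12 fell, 0 rose and 18 did not pass, and adjusted over the list alone 16 fell. The median was -0.39 (camera adjusted p = 9.62e-07, adjusted p = 0.340 with an estimated correlation and 0.0600 by fry). ISG15, a ubiquitin-like modifier, fell from 146 ± 17.9 to 103 ± 5.83 FPKM, HERC5, the ligase of ISG15, from 9.69 ± 1.18 to 6.86 ± 0.25 and IFIT3 from 35.0 ± 4.60 to 26.0 ± 1.37 (SD, n = 3 each). In control replicate 2 the list median was 0.19 above the control mean, against -0.03 and -0.12 in the other control libraries and -0.29 to -0.40 in the siGSE1 libraries. Without that replicate it was -0.29 (adjusted p = 8.62e-05).

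Genes of glycolysis and the hypoxia response had 13 members lower, 3 higher and 15 not passing of 31, and adjusted over the list alone 16 fell and 3 rose. The median was -0.20 (camera adjusted p = 2.12e-04, and adjusted p = 0.340 with an estimated correlation), and -0.11 with 8 falling under quantile normalization. The prolyl hydroxylase gene EGLN3 fell from 3.21 ± 0.04 to 1.44 ± 0.06 FPKM, hexokinase HK1 from 48.1 ± 1.76 to 33.6 ± 1.16 and aldolase ALDOC from 3.93 ± 0.27 to 1.67 ± 0.31, whereas the phosphofructokinase gene PFKL rose from 7.60 ± 0.53 to 11.1 ± 0.50 (SD, n = 3 each). Without siGSE1 replicate 2, 1 member rose. Of 40 ribosomal protein genes 19 fell, 1 rose and 20 did not pass, and adjusted over the list alone 26 fell and 1 rose. Their changes were small, with a median of -0.15 (camera adjusted p = 2.71e-10, and adjusted p = 0.340 with an estimated correlation). With TPM scaling 8 fell and the median was -0.09, under quantile normalization 10 fell and it was -0.07, and without trend or robust prior in limma 6 fell. Without control replicate 1, 12 fell, and without siGSE1 replicates 1, 2 and 3, 10, 7 and 6 fell. RPL7A fell from 417 ± 24.9 to 345 ± 12.7 FPKM and RPL3 from 294 ± 10.00 to 254 ± 6.46, and RPL11, named after its values were seen, rose by 0.17 on the log2 scale, while 0 members rose without control replicate 3 or siGSE1 replicate 1, 2 or 3. Of 28 MYC targets and ribosome biogenesis genes 10 fell, 2 rose and 16 did not pass, the same adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00309, and adjusted p = 0.427 with an estimated correlation). Without control replicate 1 the median was -0.07 and 6 fell, as many as without siGSE1 replicate 2 or 3, and with TPM scaling these values were also -0.07 and 6. The processing factor gene RRP12 had a log2 fold change of -0.42 and fibrillarin FBL of -0.31, whereas the nucleolar chaperone gene NOLC1, which carries TCGGAGA in its 3' UTR, rose by 0.75.

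Of 13 genes of the mitochondrial genome 4 fell, 0 rose and 9 did not pass, and adjusted over the list alone 6 fell. The median was -0.13 (camera adjusted p = 0.00203, and adjusted p = 0.340 with an estimated correlation), and with TPM scaling it was -0.07 and under quantile normalization it was 0 with the list's direction reversed (adjusted p = 0.836). Quantile normalization gives equal ranks equal values in every library. Fold changes of the most abundant genes are thereby drawn toward 0, so it cannot decide whether this list moved. MT-ND4, a subunit of respiratory complex I, fell from 4993 ± 152 to 4096 ± 160.1 FPKM (SD, n = 3 each). Heat shock genes had 4 of 16 lower, 1 higher and 11 not passing, and adjusted over the list alone 5 fell and 1 rose. Their median of -0.14 had a camera adjusted p of 0.0454, with an adjusted p = 0.599 with an estimated correlation, and leaving out any library but control replicate 3 ended the call, with adjusted p values of 0.0501 to 0.165 and 2 to 5 members falling, against 8 without that replicate. The call was also lost with TPM scaling (0.0973), without TMM (0.0536), with the filter at 5 FPKM (0.130), with GC and length trends removed (0.0923), under limma on log2(FPKM + 1) (0.102) and under quantile normalization (0.533). The median was -0.09 without control replicate 1, -0.07 with TPM scaling and -0.02 under quantile normalization. The chaperone gene HSPA1B fell by 0.50 and HSPB1 rose by 0.36 on the log2 scale.

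**Figure D3:**
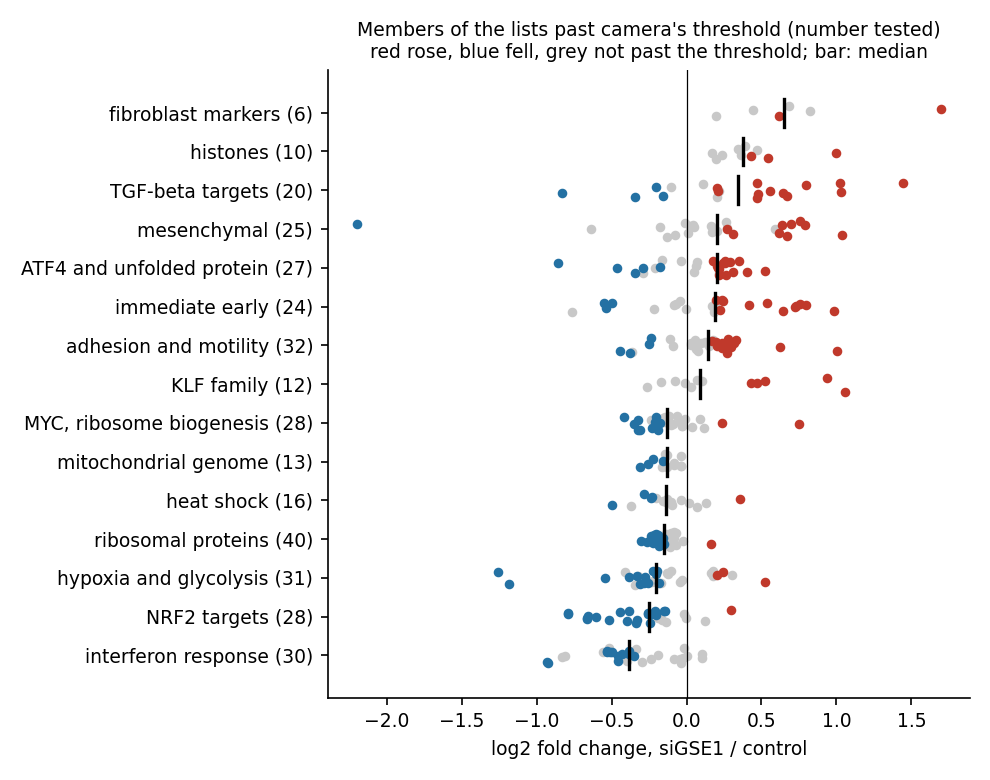
Log2 fold change (siGSE1 over control) of each tested member of the 15 gene lists past camera's threshold, with the number of tested members after each name. Red points rose, blue points fell and grey points did not pass the threshold. Bars mark medians, which ran from -0.39 for interferon response to 0.65 for fibroblast markers. The median of the mitochondrial genome list was 0 under quantile normalization, which gives equal ranks equal values.

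The remaining 14 lists tested did not pass in the list test, although single members changed. Some passed under an alternative. The mitosis list did so without control replicate 1 (adjusted p = 0.00922), with TPM scaling (0.0477) and with no low-count filter (0.0306), and nuclear oxidative phosphorylation without control replicate 3 (0.00301) or siGSE1 replicate 1 (0.0438). Cholesterol synthesis passed without control replicate 3 (0.0402), and fatty acid synthesis without control replicate 3 (0.0372) and with GC and length trends removed (0.0265). In the G1 and S phase list 7 of 29 rose and 3 fell (camera adjusted p = 0.323), among them the helicase factor CDC45 (0.41), and in the mitosis list 8 of 30 rose and 4 fell (0.130), among them the survivin gene BIRC5 (0.50). In the G1 and S phase list 4 rose and 4 fell without control replicate 3, 7 and 0 without control replicate 1, and 4 and 0, 5 and 1, and 4 and 0 without siGSE1 replicates 1, 2 and 3. In the mitosis list 9 rose and 2 fell without control replicate 1, 4 and 1 without siGSE1 replicate 1 or 3, 7 and 2 without siGSE1 replicate 2, and 11 and 2 with TPM scaling. Of 27 p53 targets 3 rose and 7 fell (0.574), and adjusted over the list alone 5 rose and 8 fell. The balance turned with TPM scaling (7 rose, 5 fell) and was even without control replicate 1 (5 and 5), and 5 rose and 8 fell without control replicate 2 and 2 and 4 without siGSE1 replicate 2. The stress cytokine gene GDF15 fell from 79.2 ± 9.94 to 49.5 ± 1.85 FPKM and the cell cycle inhibitor gene CDKN1A from 86.0 ± 8.60 to 57.3 ± 1.82 (SD, n = 3 each), whereas the repair gene DDB2 rose by 0.39. In the NF-kappaB and cytokine list 11 of 27 rose and 7 fell (0.307), with CXCL1 at 42.7 ± 10.7 and 83.2 ± 3.18 FPKM, and 4 fell without control replicate 3, siGSE1 replicate 1 or siGSE1 replicate 3 and 3 without siGSE1 replicate 2. Its median was -0.03 while the test pointed up, and the median was above 0 with TPM scaling, with the filter at 5 FPKM, without control replicate 2 or siGSE1 replicate 2, and under limma on log2 FPKM with or without quantile normalization. The medians of the p53 and lung lists, both 0.03, also differed in sign from their tests, and the p53 median was -0.01 without control replicate 2. Cholesterol synthesis had 4 of 27 rising and 10 falling (0.0992), and adjusted over the list alone 5 and 11, with HMGCS1 among those that fell. Without siGSE1 replicate 1, 4 rose and 4 fell, and without siGSE1 replicate 2, 4 rose and 5 fell. Fatty acid synthesis had 1 of 17 rising and 3 falling (0.0585), and adjusted over the list alone 1 and 5, with the synthase FASN at -0.31, and 5 fell without control replicate 3. In the nuclear oxidative phosphorylation list 2 of 33 rose and 6 fell (0.0626), with UQCRB at -0.31, and that median of -0.05 was above 0 with TPM scaling. Only 2 fell with TPM scaling and without control replicate 1, siGSE1 replicate 1 or siGSE1 replicate 3, 1 fell without siGSE1 replicate 2, and 9 fell without control replicate 3. The number that rose was 1 without control replicate 2 and 0 without control replicate 3 or siGSE1 replicate 1, 2 or 3.

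In the apoptosis list 5 of 28 rose and 2 fell (camera adjusted p = 0.355), with the inhibitor of apoptosis gene BIRC3 at 10.7 ± 1.17 and 8.34 ± 0.26 FPKM in control and siGSE1 cells (SD, n = 3 each). Without control replicate 1, 3 rose and 3 fell, without siGSE1 replicates 1, 2 and 3, 3, 2 and 3 rose and 1 fell in each, and without control replicate 2, 1 fell. Among YAP targets 4 of 24 rose and 3 fell (0.244), and adjusted over the list alone 6 and 3, with the ectonucleotidase gene NT5E higher by 0.64, and 7 rose without control replicate 2 and 8 with TPM scaling. In the neuronal list of genes silenced by REST 4 of 19 rose and 2 fell (0.143), with the neurotrophin gene BDNF higher by 0.45, and 1 fell on leaving out siGSE1 replicate 1, 2 or 3. In the lung lineage list 0 of 17 rose and 3 fell (0.630), with the transcription factor gene CEBPA at -0.55. Without siGSE1 replicate 2 or 3, 1 fell, without control replicate 1 or siGSE1 replicate 2, 1 rose, and without control replicate 2, 2 rose. Its median was below 0 with either other filter, under limma on log2 FPKM with or without quantile normalization, under DESeq2, and without any 1 library except control replicate 2. In the RNA interference list 1 of 13 rose and 2 fell (0.353), with the argonaute gene AGO4 at -0.38. None passed without control replicate 1, control replicate 3 or siGSE1 replicate 2, 1 fell and 0 rose without siGSE1 replicate 1 or 3, and the median of -0.02 was above 0 with TPM scaling, without TMM, with the filter at 5 FPKM, under limma on log2 FPKM without quantile normalization and without control replicate 1. Adjusted over the list alone the counts were the same for the apoptosis, neuronal, lung, RNA interference, G1 and S phase, mitosis and NF-kappaB lists.

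With the correlation estimated per list, camera called 0 of the 29 lists, 3 at an unadjusted p under 0.05, so no call by camera was kept in that form of the test. The estimated correlation was -0.07 for the KLF family list and -0.02 for the ATF4 list, under the preset 0.01. For these lists a higher correlation cannot be why the call was lost, and other reasons were not tested. By fry 13 were called, 10 of them among the 15 called by camera. Fry left out the mesenchymal (adjusted p = 0.0513), interferon (0.0600), fibroblast (0.0654), MYC (0.0797) and heat shock (0.271) lists and called those of cholesterol synthesis (0.0222), fatty acid synthesis (0.0128) and neuronal genes (0.0276), which camera did not. In addition, 1 other division of the 6 libraries into 3 and 3 gave 14 lists past the threshold, against 15 for the real one. Each other division has both treatments on each side but in unequal numbers, so part of the real contrast remains in it. The divisions therefore do not show how many lists chance alone would call.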

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

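The alternatives chosen only after the data were seen were scaling without TMM, edgeR's robust prior and removal of GC and length trends. The test named beforehand for a table of FPKM alone, limma on log2(FPKM + 1), became an alternative once the counts were seen. GSE1 and KLF6 kept their direction and stayed past the threshold under every alternative that gives gene values, with log2 fold changes of -1.09 to -0.85 and 0.95 to 1.12. The count of changed genes stayed within 1.5 times its main value except without siGSE1 replicate 2 (2055) or replicate 3, and leaving out 1 library gave 1863 (without siGSE1 replicate 3) to 3562 (without control replicate 2). DESeq2 called 2646 genes and the replicate block 3097, and between 57.5% and 99.9% of the calls were kept in the same direction, over all alternatives. In the quantile alternative 6 called genes had a fold change of the other sign or of 0, counted whether or not they passed there. Of 128 named genes called, 101 were past the threshold in the same direction under every alternative that tested them and 0 were called reversed. Alternatives that left a gene out were not counted against it. Genes with a mean under 5 FPKM, such as EGLN3 and SUSD2, were not tested with the filter at 5 FPKM.

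The count under the stricter thresholds was 406, and it was 670 without the low-count filter and 239 with a filter at 5 FPKM, where the set of genes tested differs. With limma it was 131 on log2(FPKM + 1), 137 with a pseudocount of 0.1, 135 with 0.5, 104 after quantile normalization and 4 without the trend and robust prior, and the cause was not tested. Leaving out 1 library gave 201 to 530, with 261, 266 and 201 without siGSE1 replicates 1, 2 and 3, where fewer samples were left. The count of 15 lists was 0 in limma camera with an estimated correlation (3 at an unadjusted p under 0.05), 13 by fry and 11 to 18 under the other alternatives, and the cause was not tested.

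Directions reversed for lists and a gene that were not called, and for 1 called list, and the cause was not tested. The CoREST list pointed up with TPM scaling (adjusted p = 0.729), without TMM (0.973) and with limma on log2(FPKM + 1) (0.925, and 0.925 without trend or robust prior), with 0.1 (0.918) and with 0.5 (0.922). Without 1 library its adjusted p ran from 0.616 to 0.993, and it reversed without siGSE1 replicate 3 (0.958). The p53 list reversed with the filter at 5 FPKM (0.944). The lung list reversed without control replicate 2, in a range of 0.342 to 0.804, and the G1 and S phase list without control replicate 3, in a range of 0.0705 to 0.993. The leukocyte marker CD14, not past the threshold, went from a log2 fold change of -0.14 to 0.16 without control replicate 2, in a range of -0.33 to 0.16. The mitochondrial genome list reversed under quantile normalization (0.836), which gives equal ranks equal values and so cannot decide on genes this abundant. Among all list results 569 were the same, 40 weaker, 11 stronger and 11 reversed, and among named genes 2547 were the same, 144 weaker and 1 reversed. At these depths, this spread and 3 libraries a group, the simulated comparison recovered 22.4% of genes at its smallest fold. It had 200 changed genes where the data had 3167 calls, which makes the adjusted threshold harder to pass. The share recovered therefore does not carry over to the data, and the part due to depth was not tested. Counts summed per gene symbol gave 3165 changed genes, and camera was not run on DESeq2 values, which gave member counts and medians of the lists alone.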

Other observations

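The tests of TCGGAGA sites, of base composition, of KLF6 sites and of GC and length in ribosomal protein genes were chosen only after the result was seen, as were the genes named in this part outside the naming rule.

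Among the deposited ontology terms, 7 were over-represented among higher genes and 18 among lower genes. A random set of either size gave 0, but its genes were drawn independently, so it does not cover genes that move together. Several of the lower terms share the same ribosomal protein genes. Axon guidance genes, which include many regulators of the cytoskeleton and matrix, had 62 of 220 higher against 28.7 expected (hypergeometric adjusted p = 2.06e-06), among them the basement membrane collagen gene COL4A4 (2.71 ± 0.04 to 4.83 ± 0.16 FPKM, SD, n = 3 each). Extracellular matrix organization had 23 of 78 higher against 10.2 expected (adjusted p = 0.0200), with COL7A1, the collagen of anchoring fibrils, at 17.1 ± 5.19 and 37.8 ± 2.57 FPKM. EGF receptor signaling had 28 of 95 higher against 12.4 expected (adjusted p = 0.00975).

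Lower genes were rich in translational initiation, with 33 of 105 against 11.5 expected (hypergeometric adjusted p = 1.38e-05), glycolytic process, with 15 of 36 against 3.94 (adjusted p = 4.43e-04), and defense response to virus, with 26 of 84 against 9.19 (adjusted p = 3.51e-04). Positive regulation of interferon-beta production had 10 of 21 lower against 2.30 expected (adjusted p = 0.00345). Its members include the RNA sensor genes DDX58 (log2 fold change -0.39) and IFIH1 (-0.46) and the RNA polymerase III subunit genes POLR3F (-0.85), POLR3A (-0.41) and POLR3G (-0.82). NFE2L2, the gene of NRF2 itself, fell from 20.5 ± 0.75 to 15.8 ± 0.30 FPKM (SD, n = 3 each), a log2 fold change of -0.40 (SE 0.05, edgeR adjusted p = 6.40e-05), and its inhibitor gene KEAP1 had -0.21 (adjusted p = 0.0173).

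Genes with the sequence TCGGAGA in the 3' UTR were higher in siGSE1 cells, by 0.19 on the log2 scale over 233 genes (t = 8.36, permutation p = 0.005, the smallest that 200 permutations give), and 84 of 1625 higher genes carried it against 29.5 expected. Counting TCGGAGA or CGGAGAA in the 3' UTR or coding sequence, 528 of them (32.5%) were carriers against 18.9% of all genes searched, and among genes with neither 1097 rose and 1157 fell. Unlike t, these counts of carriers were not adjusted for length, and longer sequences hold a site more often. By exonic length, the class of the longest genes had a median log2 fold change of 0.04 and that of the shortest -0.04. The part of the excess due to length was not tested. Repression of carriers by the control siRNA through its seed may contribute and stays open, since genes with the 8-base TCGGAGAA lay 0.135 above those with TCGGAGA alone (one-sided permutation p = 0.0077), but carriers of CGGAGAA, the end of the 8 bases, were already seen to lie higher (t = 6.72), so this comparison does not decide. Base composition is argued against, since 419 sites with the same bases in another order had a median t of -0.04, and so is a match of KLF6 to TCGGAGA or CGGAGAA, held by 0 of its 7 annotated transcripts, but 6 of them hold another site above every permutation, GGAGAAA (t = 7.74, carried by 463 of 1625 higher genes, 28.5% against 20.1% of all genes searched), so a match of KLF6 stays open. The siRNA sequences are not given, so the identity of the seed was not tested, and effects of the lower GSE1 level stay open for carriers and all other genes alike.

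Genes lower in siGSE1 cells more often carried TTGTTGA in the 3' UTR, 19.9% of 1324 against 14.1% of all genes, shares that were not adjusted for length. Repression by seed matches of the siRNA against GSE1 may contribute, since 3 of the 16185 sites lay below every permutation. TTGTTGA had the lowest t (-5.86, permutation p = 0.005, the smallest that 200 permutations give). Its effect was -0.05 on the log2 scale, and most lower genes do not carry it. The others were AGATGGT (t = -5.45, carried by 220 of 1324 lower genes) and TGATGGT (t = -5.15, carried by 179). Both hold GATGGT, which TTGTTGA does not. How many lower genes carry any of the 3 was not tested, nor was a match of the siRNA to them, as its sequence is not given. A trend in GC content or gene length is argued against as the whole cause of higher and lower genes, since 90.1% of the calls were kept in the same direction with the trend removed. An effect of lower GSE1 itself stays open and was not separated from effects of the siRNA, since the labels name no second siRNA against GSE1.

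Of 40 ribosomal protein genes 19 fell, 1 rose and 20 did not pass, with a median of -0.15, and 12 fell without control replicate 1 and 10, 7 and 6 without siGSE1 replicates 1, 2 and 3. Because these are short genes, a length or GC trend could produce this, and of 5 length classes the shortest genes had a median of -0.04 and the longest 0.04. With the trend removed per library the list's median was -0.16 (camera adjusted p = 5.12e-08), which argues against it as the whole cause, although camera does not call the list with an estimated correlation (adjusted p = 0.340 before the removal). A change in RNA composition between groups stays open, since the mitochondrial share of counts was also lower, and no biological explanation beyond the siRNA group was tested.

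Of the 10 divisions of the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes (3167, highest other 0 by edgeR, with 288 to 436 at an unadjusted p under 0.05 against 5193). For the stricter thresholds it was also 1 (406, highest other 0), and for the lists 1 (15, highest other 14, from control replicates 1 and 2 with siGSE1 replicate 2 against the rest). With 10 divisions the share cannot fall under 0.05. Each other division has both treatments on each side. For single genes this adds the treatment difference to the spread within groups, which by itself lowers the number of calls. For lists part of the real contrast remains. The divisions therefore do not measure what chance alone would give. Among the lists called, those of adhesion and motility, fibroblast markers and heat shock each had a smaller unadjusted p in 3 other divisions than in the real one, the mesenchymal list in 2, and the interferon, immediate early, ATF4, MYC and histone lists in 1. The TGF-beta, NRF2, ribosomal protein and interferon lists each passed in 6 of the other divisions and the KLF family list in 0.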
